A study of Homo sapiens with 45 samples.

How the data were processed

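RNA was measured in 45 samples of NK, CD8 T and CD4 T cells. Per the labels' protocols, cells were purified from blood by negative selection, co-cultured with tumor cells, and their total RNA was made into SMART-seq libraries, a method for small RNA amounts that copies full-length transcripts from the poly(A) tail. The table the authors deposited is named as FPKM, fragment counts scaled by transcript length and by the total of mapped fragments. The submitters' processing notes name the hg38 genome build and DESeq2, without saying what DESeq2 was used for. The aligner, the counting tool and the gene annotation are not given in the sources used here.

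Apart from a look at the range and sum of each column to check its unit, only the header line and the column of gene IDs were read, with Python 3.11.15. The outcome of that look is not reported here, so the unit rests on the name given by the authors. Each of the 47 column headings was compared with the title, description, source name and characteristics of each sample. The number of matches was 0, so all 47 value columns were left unused. Samples were grouped by cell type, treatment and time as their titles give them, and donors were counted from the donor label. Gene IDs were compared with the symbols of a reference table of human gene names, and the members of 23 gene lists with the gene IDs, in both cases as whole strings. The genes to be named were to be chosen by a rule fixed before the data were examined, from the largest changes in each comparison and the fixed lists; the rule was not applied.

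A linear model on log2-transformed values with the donor as a block had been planned for each comparison, with alternatives for the pseudocount, the filter on low values, the scaling, the block, the libraries in the fit, the variance prior and the donors included. None of these fits was run, since each needs columns assigned to groups. No model was fitted, so no test on simulated data was made.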

Results

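The series measured RNA in human lymphocytes from blood after co-culture with tumor cells, with engager molecules in the treated groups. An engager is a protein that binds a receptor on a cytotoxic lymphocyte and an antigen on a tumor cell, so that the 2 cells are held together. The labels listed 45 samples in 15 groups of 3 samples each. NK cells made up 27 samples in 9 groups, CD8 T cells 9 samples in 3 groups, and CD4 T cells 9 samples in 3 groups. NK cells received one of the 4 treatments labelled NKCE-I+IL2, NKCE-II, NKCE-III and NKCE-IV. The T cells received CD3xCLL1, whose label names CD3, the signalling part of the T cell receptor complex, and CLL1, the product of CLEC12A, a myeloid surface antigen. Samples were taken at 16 h and at 64 h. Control samples were listed at 16 h for each of the 3 cell types, and 0 control groups were listed at 64 h. The titles of the controls read CTRL and do not say what these cells received.

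The donor labels named 4 blood donors over the whole series, with 3 donors for each cell type. NK and CD8 samples came from the same 3 donors. CD4 samples shared 2 donors with the NK samples and 2 with the CD8 samples. Each donor contributed to every group of a cell type, so treated and control samples are paired by donor. The design therefore sets each engager against the control of the same cell type at 16 h. It also sets 64 h against 16 h within each treatment, and the 4 NK cell treatments against each other at each time. The T cell responses can be set against the NK cell responses at 16 h. NKCE-I was listed only together with IL2, so the parts of that treatment cannot be told apart. NK cells and T cells received different engagers, so cell type and engager cannot be told apart between them either. CD8 and CD4 T cells both received CD3xCLL1, so their responses can be set against each other under the same engager. With 0 control groups at 64 h, a change from 16 h to 64 h mixes engager response with time in culture.

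None of these comparisons was made, and no expression level, fold change or p-value is reported. The deposited table held 58270 gene rows and 47 value columns, 2 more than the number of samples in the labels. The columns were headed with bare running numbers. The number of column headings that matched the title, description or another label of a sample was 0. Column order and expression of marker genes were not used to assign columns to cell types, treatments or donors. The depth behind the values is unknown.

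The gene rows included most of the genes in the lists drawn up for the planned comparisons. Of 485 genes in 23 lists fixed before the data were examined, 480 had a row in the table under the symbol given. All 16 cytotoxic effector genes had a row, among them GZMB and PRF1, which encode a granule protease and the pore-forming protein perforin. All 31 cytokine and chemokine genes had one, among them IFNG, which encodes interferon gamma. The same held for the 23 NK cell receptor genes, such as NCR1 and FCGR3A, and for the 28 cell cycle genes. All 25 genes listed as markers of myeloid leukaemia cells, CLEC12A among them, had a row, as did the 16 markers of T cells and the 15 of NK cells. In the oxidative phosphorylation list 24 of 27 symbols had a row, in the type I interferon list 27 of 28, and in the interferon gamma list 25 of 26. Synonyms were not searched for the list genes, so a gene without a row may stand under another name. These counts describe which symbols were listed in the table, not whether the genes were expressed.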

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

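The alternatives below for matching column headings and gene IDs were chosen after seeing the data. The number of column headings that matched a sample was 0 when a whole label had to equal the heading, 0 when the heading could stand anywhere in a label, and 0 when it was searched in the digits of a label alone. Of the 58270 gene IDs, 31903 equalled a current symbol of the reference table, 34503 a current symbol or a listed synonym, and 33631 a current symbol once the endings that mark the position of repeated names were removed. Other settings fixed before the data were examined, for the pseudocount, the filter on low values, the scaling, the donor block, the libraries in the fit, the variance prior, the correlation between genes, the shared controls and the donors included, were not run. No paired analysis was made, because no value column matched a sample by name, and other ways of assigning columns to samples and donors were not used.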
